A study of Mus musculus with 24 samples.

How the data were processed

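Gene expression was measured in the oesophagus of wild-type mice and of mice that lack Nrf2, the transcription factor encoded by Nfe2l2. The mice were 12 weeks old, male and of the C57BL/6J strain per the labels, and were taken without reflux or after 4 weeks of gastric, duodenal or mixed reflux. Each of the 8 groups held 3 arrays, 24 in all. On every array the oesophageal RNA carried the dye Cy5, and a commercial mouse reference RNA pooled from 11 cell lines carried Cy3, per the labels. No dye was swapped, so a dye effect specific to a gene stays in its ratio to the reference, but falls out of a difference between groups. The labels name the tissue of 7 groups as whole oesophagus and that of Nrf2-null mixed reflux as oesophageal epithelium. They call the arrays of a group biological replicates, and the p-values use a gene's spread pooled over the groups.

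The deposited scanner files hold, for each of 45018 spots per array, the mean intensity and the local background intensity of both dyes on a linear scale, per the file headers of the Agilent Feature Extraction software. The same files hold a log10 ratio of Cy5 over Cy3 made by that software from its processed intensities, per the file headers. The file headers name software version 10.5.1.1 and mouse genome build mm7 for the 2 arrays of slide 1, and version 10.7.3.1 and build mm9 for the other 22 arrays, while the submitters' processing notes name Agilent Feature Extraction 9.1. The deposited values give a log ratio of Cy5 over Cy3 per spot and array. These log2 values were normalised by the authors in a way not given in the sources used here. Their slope on the software's log10 ratio was 2.68 to 3.14 and their direction the same on all 24 arrays, so the scale was read as log2, and the column medians lay between 0 and 0.07.

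Ratios were computed anew from the deposited intensities with limma 3.58.1 in R 4.3.3. The background was corrected with the normexp method and an offset of 50, and each array was normalised by loess with the 1639 control spots at weight 0. Control spots were then left out, which left 43379 spots of 41174 probes. Spots that the scanner software marked as outliers were left out, which removed 13.0% and 11.8% of spots on the 2 arrays of slide 1, both of the wild type without reflux, and 0.293% to 0.659% elsewhere. Many bright genes were therefore measured on only 1 or 2 arrays of that group. Local backgrounds marked as outliers were replaced by the array's median background. This choice was made after seeing the data: with the local backgrounds as read, 8 and 7 spots on wild type without reflux replicates 1 and 3 lay more than 100 units below smeared backgrounds, and the fitted mean of the Cy5 background model fell to -813 and -1075 on those arrays. After the replacement it was -13.8 to -5.46 over all 24 arrays.

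Probes were named through the RefSeq accessions, symbols and synonyms of the mouse reference gene table. Of the probes, 26918 matched by accession, 5082 by symbol and 817 by synonym, and 8357 kept the name in the files. Repeat spots of a probe were averaged, and a gene with several probes was represented by its brightest probe. Among the called genes with several probes, 0% to 30.6% per comparison had another probe whose difference had the opposite sign. A gene was tested when a probe was well above background in Cy5 on all arrays of at least 1 group, which left 20555 genes. Coordinates are those of the probes in build mm9, per the file headers.

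The 3 arrays of Nrf2-null mixed reflux were far closer to each other than other arrays. The variance of their pairwise differences between probes was 1.63 to 2.61 times that between repeat spots, against 5.85 to 470 times for the 21 pairs within other groups, and they correlated at 0.996 to 0.997. They were averaged and counted as 1 sample, which left 22 samples. That group has no spread of its own, and its tests take the spread of the other groups. This, too, was chosen after seeing the data. The comparisons, tests, 36 gene lists and the rule for named genes were fixed before the data were examined.

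One model with a mean per group was fitted to all samples with lmFit and eBayes (14 residual and 2.93 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were Nrf2-null against wild type in each of the 4 reflux conditions and as their mean, each reflux type against no reflux within each genotype, and an F test of whether the genotype difference depended on reflux. A value after ± is the standard error of the fit unless called an SD. Where a gene was not well above background on any array of a group, the difference is given as "at least N-fold". This sets the brighter group's mean Cy5 level against the mean, in the dimmer group, of the higher of each array's lowest level well above background and the gene's own level. It is open to dye bias, and where it exceeded the fold of the ratios to the reference, the log2 difference is given in its place, and which channel is off stays open.

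Gene lists were tested against all other genes with camera on the moderated statistics and a preset correlation of 0.01, and again with an estimated correlation, each adjusted over the 36 lists. A list's shift is its mean log2 difference minus that of the other genes. A list's level on an array is the mean of the members measured there, and as arrays of slide 1 measured fewer, differences of levels can part from the mean difference in the fit. The lists covered signalling, stress, metabolic, clock and cell cycle genes, states and regions of epithelium, and the other cell types that the tissue could hold. Of 661 members, 655 had a probe. The Nrf2 targets and the 5 lists with the smallest adjusted p are described for each comparison.

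Named genes follow a rule. Nfe2l2 is named in each comparison. Among genes with a symbol, adjusted p under the threshold and all arrays of one group above all arrays of the other (for the mean, the same direction in all 4 conditions), the 8 largest rises and 8 largest falls are named. Up to 4 members with the smallest adjusted p of each described list and the 8 genes with the smallest interaction p complete it. Some genes that the rule names are not reported here.

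The median Cy5 intensity per array was 81.8 to 249 and that of Cy3 229 to 294, and 57.4% to 74.7% of spots were well above background in Cy5. The arrays lay on 7 slides scanned on 3 days. Slide 1 (day 1) held wild type without reflux 1 and 2. On day 2, slide 2 held wild type without reflux 3 with all 3 of wild-type gastric reflux, and slide 3 Nrf2-null without reflux 1 and 2. The other 16 arrays, on slides 4 to 7, were scanned on day 3. Slide and scan day were fitted as blocks where the comparison could be estimated, and comparisons were repeated within each slide or day that held both groups.

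In simulations with the real spread, the duodenal reflux genotype comparison recovered 10.4%, 50.7% and 93.9% of genes changed by 0.5, 1 and 2 log2 units. Of its calls 6.4% were false. For the mean over conditions the shares were 50.7%, 91.0% and 97.0%, and for mixed reflux 0%, 22.4% and 69.7%. With no gene changed, 20 draws gave at most 1 call. The alternatives chosen beforehand were the scanner software's processed intensities, the deposited value table, median centring, Aquantile, no filter on dim probes, the mean of a gene's probes, slide and replicate blocks, only the 2 groups compared, leaving out slide 1 and leaving out each sample. Others were chosen later. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and data.table version 1.17.8 was used for reading.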

Results

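Expression was profiled in the oesophagus of wild-type and Nrf2-null mice kept without reflux or exposed for 4 weeks to gastric, duodenal or mixed reflux, on 24 arrays in 8 groups of 3. Values are log2 ratios of oesophageal RNA to a common reference, and the number of arrays limits their precision. The comparison of the genotypes in each of the 4 conditions is the one the series design states, and it asks which genes depend on Nrf2, the transcription factor that switches on antioxidant and detoxification genes. The 3 arrays of Nrf2-null mixed reflux were counted as 1 sample, so each comparison with that group rests on 1 sample against 3.

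**Figure D1:**
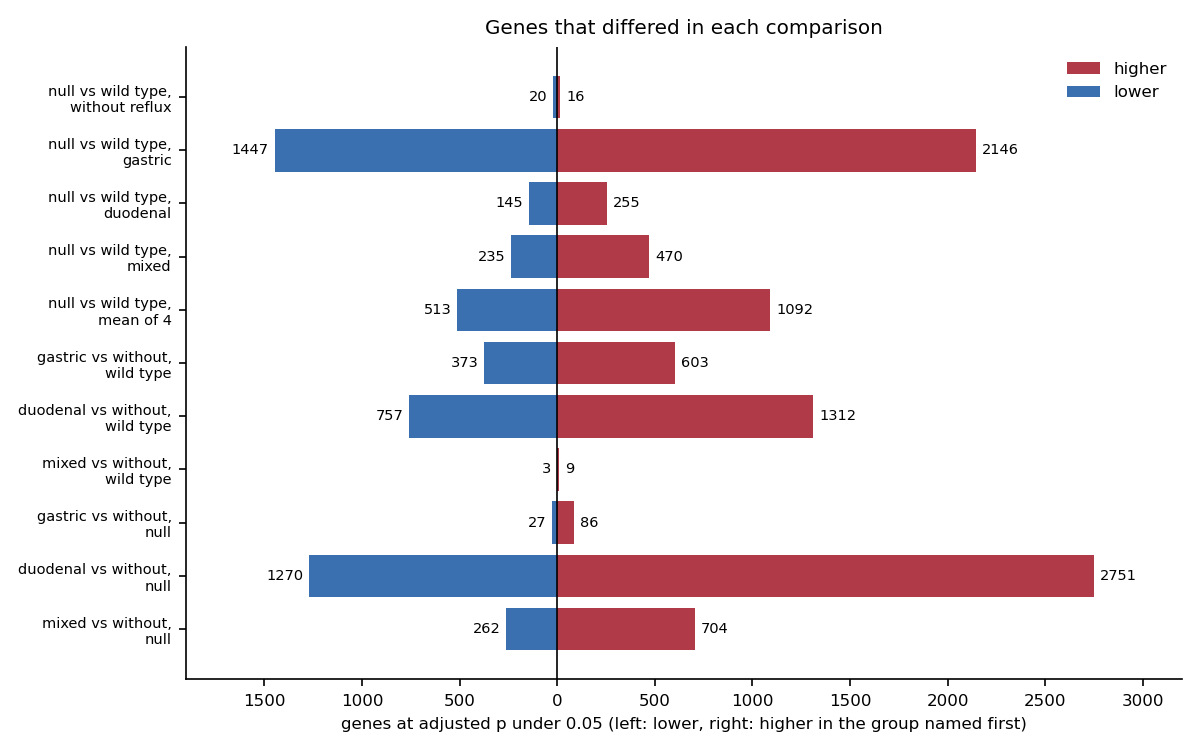
Number of genes higher and lower at adjusted p under 0.05 in each of the 11 comparisons (bars start at 0). The counts run from 12 genes for mixed reflux in the wild type to 4021 for duodenal reflux in the Nrf2-null oesophagus.

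The targeted gene was checked first. Nfe2l2 lay between 1.45 and 2.18 on the 10 wild-type arrays that measured it and between -3.81 and -2.83 on all 12 Nrf2-null arrays, so each array that measured it carried the level of its label, and the 2 arrays of slide 1 did not measure it. The probe lies on chromosome 2 at 75513917 to 75513976 (mm9). A second probe of the gene, at 75513771 to 75513830, also separated the genotypes, while another, at 75529947 to 75530006, did not. The part of the gene that was removed is not given in the sources used here, and a probe outside it checks nothing. The difference was -4.99 ± 0.33 without reflux (adjusted p = 4.59e-06), -5.21 ± 0.24 under gastric (1.76e-08), -5.33 ± 0.24 under duodenal (1.26e-08) and -5.62 ± 0.33 under mixed reflux (8.71e-07). Within a genotype no reflux type changed Nfe2l2: the differences ran from -0.39 ± 0.33 to 0.39 ± 0.33, with adjusted p of 0.511 to 0.968.

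**Figure D2:**
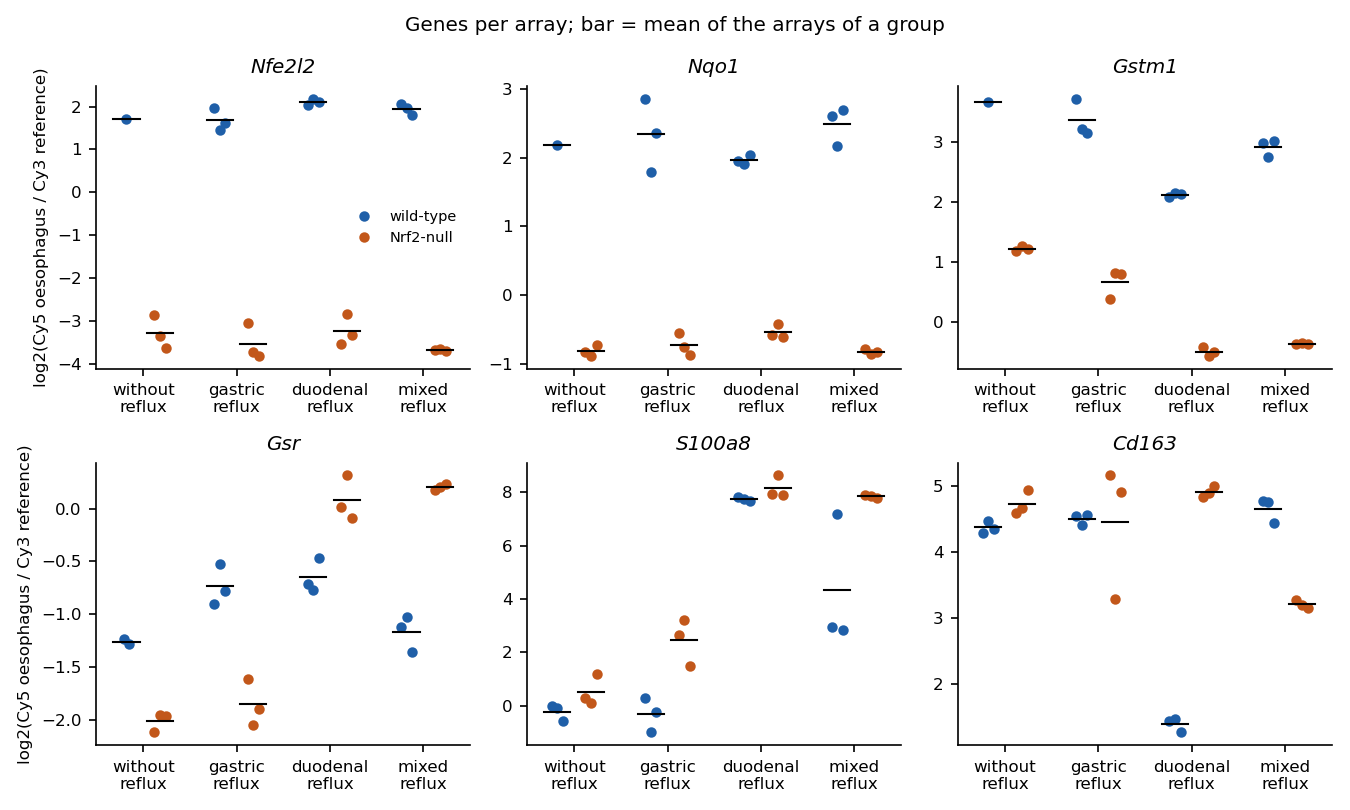
Log2 Cy5/Cy3 ratio of 6 genes on each array by group (points are arrays, bars are group means; the 3 arrays of Nrf2-null mixed reflux count as 1 sample). Nfe2l2 lies between 1.45 and 2.18 on wild-type and between -3.81 and -2.83 on Nrf2-null arrays.

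Without reflux, 20 genes were lower and 16 higher in the Nrf2-null than in the wild-type oesophagus. The largest falls were in detoxification enzymes: the quinone reductase Nqo1 (-2.99 ± 0.30, adjusted p = 0.000183), the aldo-keto reductase Akr1b8 (-2.57 ± 0.31, 0.00127), and the glutathione transferases Gstm1 (-2.45 ± 0.22, 7.13e-05) and Gsta3 (-2.42 ± 0.23, 3.68e-05). Mgst1 (-2.30 ± 0.38), Gstp1 (-2.10 ± 0.26) and Gclc (-2.36 ± 0.41), the catalytic subunit of the enzyme that limits glutathione synthesis, fell too. Of 37 measured Nrf2 target genes, 7 were lower and 0 higher (13 lower when adjusted over the list alone), and the list was shifted by -0.86 (adjusted p = 2.44e-20, and adjusted p = 0.0119 with an estimated correlation). The rises were led by the RNA-binding protein gene Rbm45 (2.98 ± 0.26, 2.46e-05), Mal (2.10 ± 0.38) and Olah (1.96 ± 0.29). Natd1 (1.60 ± 0.27), Calcb (1.55 ± 0.28), Cap1 (1.43 ± 0.18) and Fer1l4 (1.28 ± 0.16) also rose.

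Other lists shifted in that comparison without a member that passed alone. The cell cycle list was shifted by -0.30 (adjusted p = 3.86e-06, and adjusted p = 0.227 with an estimated correlation). Of its 30 members, 4 were lower adjusted over the list alone and 8 at an unadjusted p under 0.05. Cdc20, an activator of mitotic exit, differed by -1.13 ± 0.27 (adjusted p = 0.192), and Ccna2, Plk1 and Birc5 by -0.72, -0.68 and -0.81. Macrophage (0.71), skeletal muscle (1.09) and fibroblast genes (0.52) were shifted upwards, with adjusted p of 0.000327, 0.000412 and 0.00734, and adjusted p of 0.874, 0.88 and 0.874 with an estimated correlation. In limma's test at an unadjusted p under 0.05, these lists held 2, 0 and 0 higher genes. The mean of the skeletal muscle list was 2.35 ± 0.48 (SD, n = 3) in the null and 1.09 ± 0.33 (SD, n = 3) in the wild type. The macrophage gene Mrc1 differed by 1.81 ± 0.74, Ckm by 1.78 ± 0.96 and the matrix gene Lum by 1.74 ± 0.93, none past the threshold. With scan day as a block the shifts were -0.85 for Nrf2 targets, -0.35 for the cell cycle, 1.07 for macrophage, 1.12 for skeletal muscle and 0.64 for fibroblast genes. Blood, unfolded protein response, mast cell and interferon-stimulated genes differed by 0.67, 0.28, 0.36 and 0.47 on average, with adjusted p of 0.00734, 0.00734, 0.0354 and 0.0389, and adjusted p of 0.227, 0.227, 0.632 and 0.948 with an estimated correlation. These calls were lost or turned in 4, 3, 9 and 10 of 23 alternatives.

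With scan day as a block 16 genes passed, and within day 2, which held 1 wild-type and 2 null arrays, 19 passed. The count was 21 without wild type replicate 2, 23 without wild type replicate 3 and 17 without null replicate 2. It was 310 with the muscle list as a covariate, 247 without the 2 arrays of low Cy5 signal, 59 with mixed reflux as 3 samples and 3054 with local backgrounds as read. Without wild type replicate 3 the macrophage shift was 0.41 and the fibroblast shift 0.29, neither with a call. With each array centred on its median in place of loess 25 genes were higher and 3 lower, while the median of all genes moved from -0.01 to 0.37. Nfe2l2, Nqo1, Akr1b8, Gstm1, Gstp1 and Natd1 rested on 1 wild-type array, and Gclc and Mgst1 on 2.

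Under gastric reflux 2146 genes were higher and 1447 lower in the Nrf2-null oesophagus. Rbm45 (3.36 ± 0.26, adjusted p = 2.04e-06), the inflammatory cytokine Il1b (3.11 ± 0.80, 0.0166), Plac8 (3.06 ± 0.63) and Slfn4 (at least 4.06-fold) rose most. The alarmin S100a8 (2.77 ± 0.80) and Upk3bl (2.48 ± 0.29) followed. Tspan13 (-3.73 ± 0.80, 0.00729), Cilp (-3.40 ± 0.80) and Synm (-3.20 ± 0.68) fell most. Timp2 (-3.10 ± 0.58), Nqo1 (-3.06 ± 0.21, 2e-06) and Gclc (-2.86 ± 0.36) came next. Among Nrf2 targets 21 of 37 were lower and 0 higher (26 lower adjusted over the list alone), with Gstm1 (-2.70 ± 0.16), Akr1b8 (-2.56 ± 0.22) and Gstm3 (-2.20 ± 0.19) among them. The list shifted by -1.03 (adjusted p = 1.32e-16, and adjusted p = 0.066 with an estimated correlation).

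In the same comparison 17 of 30 cell cycle genes were higher and 0 lower (24 higher adjusted over the list alone). They included the centromere histone Cenpa (1.38 ± 0.20, adjusted p = 0.00126), Tpx2 (0.87 ± 0.16) and the mitotic kinases Aurkb (1.07 ± 0.19) and Bub1 (0.78 ± 0.14). Some energy genes were lower: 10 of 49 oxidative phosphorylation genes, such as Uqcrfs1 (-1.11 ± 0.21) and Atp5g3 (-1.03 ± 0.22), and 4 of 15 TCA cycle genes, such as Mdh2 (-1.28 ± 0.25) and Ogdh (-1.21 ± 0.28), with 0 higher in either. Adjusted over the list alone, 12 and 6 were lower. Of 19 fibroblast and matrix genes 7 were lower and 0 higher (10 lower adjusted over the list alone), including Fbn1 (-1.96 ± 0.48) and Fn1 (-0.92 ± 0.24). The shifts were 0.59 for the cell cycle (adjusted p = 1.99e-08), -0.50 for oxidative phosphorylation (1.73e-07), -1.03 for fibroblast genes (2.86e-05) and -0.71 for the TCA cycle (8.62e-05). With an estimated correlation none of the 4 passed (adjusted p = 0.164, 0.632, 0.632 and 0.632). The mean of the skeletal muscle list, whose cells are rich in mitochondria, was 0.65, 4.54 and 4.52 on the wild-type and 4.65, 1.73 and 1.80 on the null arrays. Smooth muscle, endothelial, T and NK cell, basal keratinocyte and squamous genes differed by -0.66, -0.58, 0.68, 0.51 and 0.67 on average (2 of 10 and 4 of 15 lower, 3 of 17, 4 of 15 and 8 of 29 higher, 1 squamous gene lower), with adjusted p of 0.0281, 0.00768, 0.0416, 0.0218 and 0.000241, and adjusted p of 0.682, 0.632, 0.682, 0.632 and 0.632 with an estimated correlation.

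The wild-type arrays under gastric reflux were scanned on day 2 and the null arrays on day 3, so no day held both groups. With scan day as a block, estimated from the other groups, 9 genes passed, with list shifts of -1.05 for Nrf2 targets, 0.52 for the cell cycle, -0.42 for oxidative phosphorylation, -1.23 for fibroblast and -0.82 for TCA cycle genes. The count was 1021 without wild type replicate 2, 1171 without wild type replicate 3, 1 in a fit of only these 6 arrays and 1895 after median centring (658 higher and 1237 lower, with the median of all genes at -0.06 against 0.11). Of the 35 genes that passed and that the naming rule takes, 6 still passed with the scan day block. Null replicate 2 is labelled male and its sex-linked genes disagreed with that, and 2758 genes passed without it.

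Under duodenal reflux 255 genes were higher and 145 lower in the null oesophagus. The scavenger receptor Cd163 (3.52 ± 0.31, adjusted p = 1.13e-05), the macrophage product Retnla (3.15 ± 0.46, 0.00237), and Rbm45 (2.89 ± 0.26) rose most. The neutrophil product Retnlg (2.77 ± 0.50), F13a1 (2.76 ± 0.48), Ppbp (at least 5.75-fold), Has1 (2.66 ± 0.48) and Pbp2 (2.42 ± 0.30) came next. The aldo-keto reductase Akr1c18 (-3.12 ± 0.46, 0.00222), Esd (-2.68 ± 0.34), Gstm1 (-2.61 ± 0.16, 4.77e-07), Nqo1 (-2.50 ± 0.21), Gstm3 (-2.40 ± 0.19), Fmo9 (-2.16 ± 0.35) and Gsta3 (-2.10 ± 0.23) fell most. With the scanner software's processed signals, Fmo9 differed by 0.51. Of 37 Nrf2 targets 9 were lower and 1 higher (23 and 1 adjusted over the list alone), with a shift of -0.95 (adjusted p = 7.1e-21, and adjusted p = 0.0258 with an estimated correlation).

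Some inflammatory and wound genes were higher in the null under duodenal reflux. Of 22 genes of wounded epithelium 5 rose and 0 fell (8 rose adjusted over the list alone), such as the cytokine Il24 (1.60 ± 0.18, adjusted p = 0.000119), the collagenase Mmp13 (2.08 ± 0.36) and Mmp9 (1.15 ± 0.27). Of 27 NF-kB targets 2 rose (13 adjusted over the list alone), namely the chemokine Ccl20 (1.19 ± 0.22) and Icam1 (1.11 ± 0.24), while Il6 (1.97 ± 0.50, adjusted p = 0.0503) did not pass. Of 16 neutrophil genes 3 rose (7 adjusted over the list alone): Retnlg, the cytokine receptor Csf3r (1.72 ± 0.34) and the collagenase Mmp8 (1.57 ± 0.36). The shifts were 0.61, 0.60 and 0.68 for NF-kB, wounded epithelium and neutrophil genes, with adjusted p of 5.56e-06, 2.06e-05 and 0.00223, and adjusted p of 0.457, 0.199 and 0.512 with an estimated correlation. The squamous differentiation list was shifted by 0.36 (adjusted p = 0.00305, and adjusted p = 0.975 with an estimated correlation). In limma's test 0 of its 29 genes passed and 7 were higher at an unadjusted p under 0.05, and Crct1 and Sprr1b differed by 1.02 ± 0.36 and 0.93 ± 0.37. Blood genes averaged 1.41 in the null and 0.35 in the wild type (1 of 5 higher, adjusted p = 0.0147) and fibroblast genes -0.83 and -1.47 (1 of 19 higher, 0.00305), with adjusted p of 0.452 and 0.975 with an estimated correlation. Neither call was kept without null replicate 1.

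All 6 arrays of this comparison were scanned on day 3, and 367 genes passed within that day. The count was 98, 130 and 123 without wild type replicates 1, 2 and 3, and 229 and 180 without null replicates 2 and 3. It was 2676 with scan day and 5187 with slide as a block, and 29 after median centring. Within the day the shifts were -0.95, 0.61, 0.60, 0.68 and 0.36 for Nrf2 targets, NF-kB, wounded epithelium, neutrophil and squamous genes. The squamous shift was 0.11 without null replicate 2 and 0.11 without the 2 arrays of low Cy5 signal, neither with a call. With slide as a block the 5 were -1.34, 0.63 (adjusted p = 0.113), -0.17 (0.877), 0.74 (0.0943) and 1.16.

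Under mixed reflux 470 genes were higher and 235 lower in the null sample. The retinoic acid-forming dehydrogenase Aldh1a3 (4.95 ± 1.09, adjusted p = 0.0175), Pbp2 (4.55 ± 0.43, 2.77e-05), and Bhlhe22 (4.42 ± 0.78) were highest above the wild type. The anion exchanger Slc26a4 (4.37 ± 1.02), the protease Mmp10 (4.01 ± 0.81), the immediate early gene Arc (3.99 ± 0.70) and Retnlg (3.99 ± 0.71) came next. Mboat2 (-3.65 ± 0.49, 0.001), Gsta3 (-3.52 ± 0.32), Nqo1 (-3.31 ± 0.30), Gstm1 (-3.28 ± 0.22, 2.6e-06), Gstm3 (-2.71 ± 0.27), the retinol-oxidising dehydrogenase Adh7 (-2.59 ± 0.44) and Gstm2 (-2.51 ± 0.28) were lowest. Of 37 Nrf2 targets 8 were lower and 1 higher (15 and 1 adjusted over the list alone), with a shift of -0.89 (adjusted p = 6.03e-12, and adjusted p = 0.0694 with an estimated correlation). Of 30 cell cycle genes 8 were higher (16 adjusted over the list alone), among them the replication helicase genes Mcm5 (1.38 ± 0.19), Mcm3 (1.92 ± 0.29) and Mcm4 (2.03 ± 0.31).

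Some NF-kB, wound and neutrophil genes were higher there too. Of 27 NF-kB targets 8 rose (13 adjusted over the list alone), including the granulocyte growth factor Csf3 (3.35 ± 0.56, adjusted p = 0.00297), Ccl20 (1.90 ± 0.32), and the neutrophil chemokines Cxcl1 (3.26 ± 0.55) and Cxcl2 (2.04 ± 0.44). Of 22 wounded epithelium genes 8 rose (8 adjusted over the list alone), including Il24 (2.67 ± 0.25, 2.77e-05), Mmp13 (3.29 ± 0.51) and the growth factor Areg (2.89 ± 0.54). Of 16 neutrophil genes 4 rose (9 adjusted over the list alone): Retnlg, Mmp8 (2.73 ± 0.51), Csf3r (2.36 ± 0.48) and Fpr1 (1.70 ± 0.45). The shifts were 0.79 for the cell cycle, 1.25 for NF-kB, 1.29 for wounded epithelium and 1.44 for neutrophil genes, with adjusted p of 1.03e-12, 7.76e-11, 3.31e-08 and 6e-06, and adjusted p of 0.0694, 0.0875, 0.0694 and 0.159 with an estimated correlation. Only 1 null sample, labelled epithelium (wild type: whole oesophagus), stands behind these values. Smooth muscle genes averaged 1.19 in it and 2.40 ± 0.40 (SD, n = 3) in the wild type. Skeletal muscle genes averaged 3.18 and 2.51 ± 1.1, so the tissue taken stays open.

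All arrays of this comparison were scanned on day 3, within which 617 genes passed and the 5 shifts were -0.88, 0.79, 1.25, 1.29 and 1.44. A scan day block gave 1165 genes. With slide as a block 602 passed, and the shifts were -1.34 for Nrf2 targets, 0.74 for the cell cycle, 1.47 for NF-kB, 0.64 (adjusted p = 0.106) for wounded epithelium and 1.71 for neutrophil genes. The count was 383 and 326 without wild type replicates 1 and 3, 1 in a fit of only these arrays, 341 after median centring and 4317 with the 3 null arrays counted as 3 samples.

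Averaged over the 4 conditions, 1092 genes were higher and 513 lower in the null oesophagus. Nqo1 (-2.97 ± 0.13, adjusted p = 2.11e-09), Gstm1 (-2.76 ± 0.10, 1.79e-10), Gsta3 (-2.33 ± 0.13), Gstm3 (-2.30 ± 0.12), Esd (-2.18 ± 0.19), Gclc (-1.99 ± 0.21) and the carboxylesterase Ces1f (-1.85 ± 0.30) fell most beside Nfe2l2. Of 37 Nrf2 targets 25 were lower and 0 higher (29 lower adjusted over the list alone), with a shift of -0.93 (adjusted p = 9.36e-34, and adjusted p = 0.00234 with an estimated correlation). Called in each of the 4 conditions were 11 genes: Nfe2l2, Nqo1, Gstm1, Gstm3, Gsta3, Gstp1, Esd, Ptgr1, the carboxylesterase Ces1g and an unnamed transcript were lower, and Rbm45 was higher. Rbm45 (3.16 ± 0.15, 6.61e-10), whose probe lies on chromosome 2 at 76218588 to 76221536, 705 kb from the Nfe2l2 probe, was the largest rise. Pbp2 (2.21 ± 0.17), the cornified envelope gene Sprr2f (2.06 ± 0.48), Retnlg (2.00 ± 0.28), Plac8 (1.93 ± 0.36) and S100a8 (1.86 ± 0.44) followed.

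**Figure D3:**
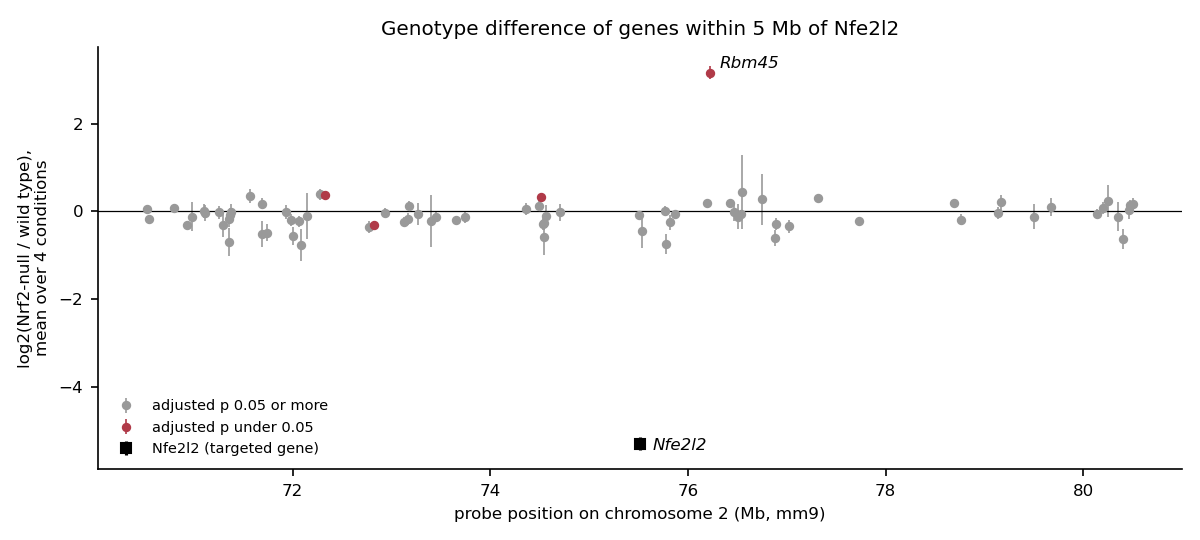
Genotype difference (log2, mean over the 4 conditions, error bars SE) of the 77 genes measured within 5 Mb of Nfe2l2 on chromosome 2 against probe position (mm9). Beside Nfe2l2, 4 genes passed: Rbm45 (3.16), Cdca7 (0.37), Hoxd12 (0.33) and Sp3os (-0.31).

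In the mean, 15 of 27 NF-kB targets were higher (20 adjusted over the list alone), such as Ccl20 (0.96 ± 0.13, adjusted p = 0.000268), and Csf3 (1.26 ± 0.22). Of 22 wounded epithelium genes 10 were higher (11 adjusted over the list alone), with Il24 (1.13 ± 0.10, 3.56e-06) and Mmp13 (1.48 ± 0.20). Among 16 neutrophil genes 8 were higher (10 adjusted over the list alone), with Csf3r (1.21 ± 0.19) and Mmp8 (1.21 ± 0.20). Of 30 cell cycle genes 9 were higher (17 adjusted over the list alone), with the nucleotide reductase genes Rrm2 (0.68 ± 0.14) and Rrm1 (0.38 ± 0.09). No member of the 4 lists was lower. The shifts were 0.61, 0.56, 0.73 and 0.23, with adjusted p of 2.28e-11, 1.63e-06, 2.28e-06 and 2.3e-06, and adjusted p of 0.125, 0.114, 0.194 and 0.247 with an estimated correlation. Under a scan day block they were 0.63, 0.56, 0.71 and 0.19, that of Nrf2 targets was -0.93, and 216 genes passed. The count was 1012 without wild-type duodenal reflux replicate 1 and 3237 without Nrf2-null gastric reflux replicate 1, and 847 after median centring. Smooth muscle genes differed by -0.49 on average (-1.21 under mixed reflux, where the tissue labels differ), macrophage genes by 0.34 and blood genes by 0.58 (0 of 10 lower, 2 of 18 and 1 of 5 higher), with adjusted p of 0.00188, 0.0151 and 0.0412, and adjusted p of 0.403, 0.645 and 0.347 with an estimated correlation. These calls were lost in 1, 3 and 11 of 39 alternatives.

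**Figure D4:**
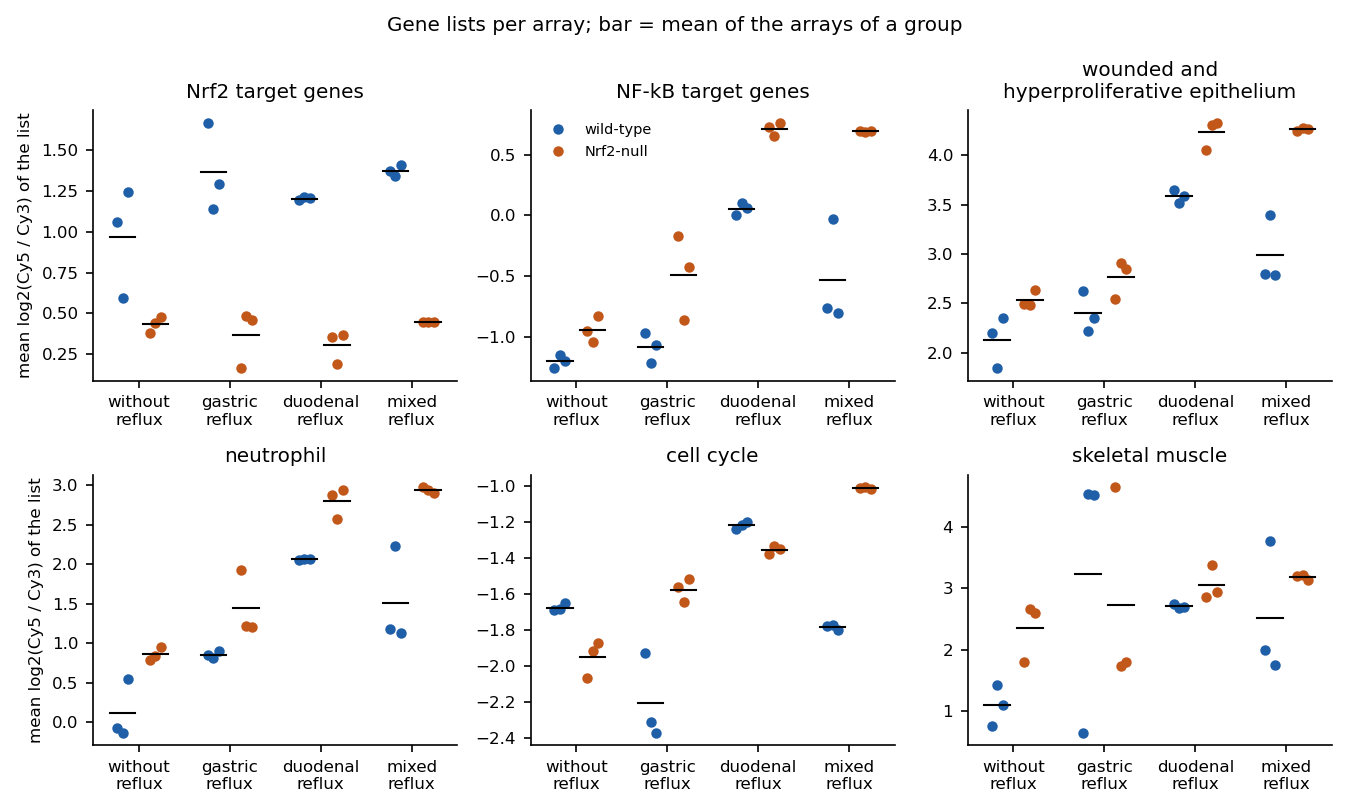
Mean log2 Cy5/Cy3 ratio of 6 gene lists on each array by group (points are arrays, bars are group means). The NF-kB mean is between -1.26 and -1.15 in the wild type without reflux and between 0.65 and 0.76 in the null under duodenal reflux.

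Gastric reflux in the wild type raised 603 genes and lowered 373 against no reflux. The rises were led by transcripts known from liver: the fatty acid-binding protein Fabp1 (5.91 ± 1.06, adjusted p = 0.0136), and the major urinary proteins Mup1 (5.63 ± 0.88, 0.0083), Mup8 (4.42 ± 0.55) and Mup10 (at least 12.4-fold). Ces3b (4.04 ± 0.63) and fibrinogen Fgg (3.91 ± 0.90) rose as well. Alb, albumin, named here outside the rule after its values were seen, was not above background on any array without reflux and rose by 3.56 ± 0.71 (0.018) in the ratio but at least 65.1-fold in Cy5 alone, a disagreement that stays open. The falls were led by Upk3bl (-2.67 ± 0.40, 0.0083), Myb (-1.80 ± 0.36), 0610040J01Rik (-1.46 ± 0.23), Wnt10a (-1.38 ± 0.19), Areg (-1.37 ± 0.38) and the cell cycle gene Cks2 (-1.33 ± 0.23). Of 30 cell cycle genes 8 fell and 0 rose (16 fell adjusted over the list alone), including Tpx2 (-0.86 ± 0.16) and Cdc20 (-1.27 ± 0.27). After median centring Tpx2 differed by 0.09, and Upk3bl and 0610040J01Rik rested on 1 array without reflux.

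Endothelial genes rose under gastric reflux in the wild type, 3 of 15 (8 adjusted over the list alone): Pecam1 (1.502 ± 0.35, adjusted p = 0.0271), Cdh5 (1.62 ± 0.41) and Tie1 (1.102 ± 0.31). Of 28 skeletal muscle genes 1 rose (2 adjusted over the list alone), Tnnt1 (3.43 ± 0.85), and the myosin Myh7 differed by 2.39 ± 0.70 without passing. Of 15 basal keratinocyte genes 2 fell (3 adjusted over the list alone), Lamb3 (-1.12 ± 0.28) and Dst (-1.08 ± 0.29, with another probe of opposite sign), while Trp63 differed by -0.83 ± 0.32. None of 49 oxidative phosphorylation genes passed in limma's test, 3 were higher at an unadjusted p under 0.05, and Cox5a and Ndufs1 differed by 1.00 and 0.67. None of 37 Nrf2 targets passed, 4 were higher and 3 lower at an unadjusted p under 0.05. The Nrf2 targets had a median of -0.12, a mean of 0.07 and no call (adjusted p = 0.493, and adjusted p = 0.829 with an estimated correlation). The other shifts were -0.58 for the cell cycle, 1.95 for skeletal muscle, 0.90 for endothelium, 0.35 for oxidative phosphorylation and -0.66 for basal keratinocytes. Their adjusted p were 1.1e-08, 2.52e-07, 2.8e-06, 0.00011 and 0.000407, and adjusted p of 0.369, 0.575, 0.496, 0.575 and 0.418 with an estimated correlation. Macrophage, fibroblast, adipocyte, blood and nerve genes differed by 0.92, 0.75, 1.62, 0.93 and 0.98 on average in the fit (0 of 18, 1 of 19, 1 of 9, 2 of 5 and 0 of 8 higher), with adjusted p of 0.000942, 0.00123, 0.00443, 0.00863 and 0.0321, and adjusted p of 0.575, 0.575, 0.575, 0.418 and 0.575 with an estimated correlation. The nerve call was lost in 12 of 25 alternatives.

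Slide 2, scanned on day 2, held 1 array without reflux and all 3 with gastric reflux, and 15 genes passed within the slide, 12 within the day, 38 with slide and 10 with scan day as a block. The shifts were 0.07 for Nrf2 targets, -0.61 for the cell cycle, 2.09 for skeletal muscle, 0.43 for endothelium, 0.39 for oxidative phosphorylation and -0.77 for basal keratinocytes in both blocks. Without wild type without reflux replicate 3 the shifts of oxidative phosphorylation (0.17) and basal keratinocytes (-0.47) had no call. The count was 50 and 39 without replicates 1 and 2 of that group, 2663, 25 and 97 without gastric reflux replicates 1, 2 and 3, and 16 without slide 1. It was 131 with the muscle list as a covariate and 3087 after median centring (96.5% higher, with the median of all genes at 0.36 against -0.06).

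Duodenal reflux in the wild type raised 1312 genes and lowered 757. The alarmin S100a8 (7.96 ± 0.80, adjusted p = 3.5e-05), urate oxidase Uox (6.36 ± 0.85), Chil3 (5.93 ± 1.08) and Spink12 (5.74 ± 0.91) rose most. Mup1 (5.72 ± 0.88), Fabp1 (5.69 ± 1.06), Nat8l (5.30 ± 0.70) and Cd163l1 (5.19 ± 0.33, 1.79e-07) followed, and Alb rose by 4.12 ± 0.71. The keratin Krt1 (-3.58 ± 0.74, 0.00574, with another probe of opposite sign), Retnla (-3.17 ± 0.51), Wfdc21 (-3.04 ± 0.64), Cd163 (-2.98 ± 0.31, 4.24e-05) and Synm (-2.40 ± 0.68) fell most. Of 27 NF-kB targets 12 rose and 0 fell (14 rose adjusted over the list alone), including Csf3 (at least 8.02-fold), Ccl20 (1.82 ± 0.22) and Birc3 (1.49 ± 0.19). Of 22 wounded epithelium genes 9 rose and 0 fell (12 and 2 adjusted over the list alone), including the stress keratins Krt16 (4.37 ± 0.47) and Krt6b (2.54 ± 0.48) and Il24 (1.22 ± 0.18). Of 16 neutrophil genes 3 rose (11 adjusted over the list alone), S100a8, lactoferrin Ltf (4.83 ± 0.73) and Csf3r (at least 1.91-fold). From the deposited value table Csf3r differed by -0.33, and Wfdc21 rested on 1 array without reflux.

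Antigen-presentation genes rose as well, 4 of 9 MHC class II genes (6 adjusted over the list alone), such as H2-Oa (1.41 ± 0.20, adjusted p = 0.00044) and the class II transactivator Ciita (2.03 ± 0.43). Of 15 endothelial genes 5 rose (12 adjusted over the list alone), including Kdr (1.94 ± 0.46) and Esam (1.03 ± 0.29). Among 37 Nrf2 targets 2 rose and 4 fell (2 and 6 adjusted over the list alone). The cystine transporter Slc7a11 (2.47 ± 0.60) rose, while Gstm1 (-1.55 ± 0.22), Gstm2 (-1.36 ± 0.28) and Gstm3 (-1.12 ± 0.27) fell. The list as a whole had a shift of -0.14 and no call (adjusted p = 0.126, and adjusted p = 0.802 with an estimated correlation). The shifts were 0.99 for NF-kB, 1.03 for wounded epithelium, 1.38 for neutrophil, 0.87 for endothelial and 1.32 for MHC class II genes, with adjusted p of 3.49e-07, 9.94e-05, 9.94e-05, 0.000122 and 0.000189, and adjusted p of 0.411, 0.411, 0.411, 0.496 and 0.44 with an estimated correlation. Skeletal muscle genes averaged 2.71 against 1.09 without reflux (0 of 28 higher, adjusted p = 0.012), smooth muscle genes 1.72 against 2.53 (2 of 10 lower, 0.00289) and macrophage genes 0.75 against 0.07 (3 of 18 higher and 1 lower, 0.0345), with adjusted p of 0.807, 0.492 and 0.802 with an estimated correlation. None of these 3 calls was kept without wild type without reflux replicate 3.

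No scan day held both groups, and the differences correlated at 0.512 over genes with that between days within Nrf2-null without reflux, so reflux cannot be told apart from scan day. A scan day block, estimated from the other groups, left 15 genes and the shifts were 1.07, 1.07, 1.35, 0.34 (adjusted p = 0.212) and 0.75, and -0.14 for Nrf2 targets, and Esam differed by -0.16. The count was 1064 and 1295 without wild type without reflux replicates 1 and 2, 1250, 933 and 884 without duodenal reflux replicates 1, 2 and 3, and 443 without slide 1. After median centring 1225 genes were higher and 294 lower, with the median of all genes at 0.18 against 0.05.

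Mixed reflux in the wild type raised 9 genes and lowered 3. The rises were S100a8 (4.54 ± 0.80, adjusted p = 0.0445), Cd163l1 (3.05 ± 0.33, 0.000584), Krt16 (2.90 ± 0.47), Fmo9 (at least 3.36-fold), S100g (at least 2.64-fold), Prap1 (1.93 ± 0.20), Clec2d (1.48 ± 0.24) and Ifi27l2b (at least 1.26-fold), and the falls included Hoxa9 (-0.99 ± 0.13). Alb differed by 1.95 ± 0.71 (adjusted p = 0.335). Among 16 neutrophil genes 1 rose (2 adjusted over the list alone), S100a8, and Cxcr2 differed by 1.31 ± 0.41. No macrophage, skeletal muscle, adipocyte or blood gene passed in limma's test. At an unadjusted p under 0.05, 3 of 18 macrophage, 0 of 28 skeletal muscle, 3 of 9 adipocyte and 3 of 5 blood genes were higher, and 2 blood genes passed adjusted over the list alone. Among them C1qc and Ccr2 differed by 0.64 and 2.07, Neb and Myoz1 by 2.36 and 1.87, Cidec and Fabp4 by 2.03 and 1.41, and Hba-a1 and Pf4 by 1.55 and 0.83.

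Wounded epithelium genes (1 of 22 higher, Krt16), and NF-kB, MHC class II and T and NK cell genes (0 higher) differed by 0.48, 0.44, 0.74 and 0.50 on average, with adjusted p of 0.0252, 0.00492, 0.00492 and 0.0372, and adjusted p of 0.64, 0.64, 0.64 and 0.789 with an estimated correlation. The shifts under mixed reflux in the wild type were 0.84 for neutrophil, 0.69 for macrophage, 1.25 for adipocyte, 0.91 for blood and 1.15 for skeletal muscle genes, with adjusted p of 0.000101, 0.00176, 0.00176, 0.00176 and 0.00192, and adjusted p of 0.467, 0.789, 0.64, 0.184 and 0.789 with an estimated correlation. Of 37 Nrf2 targets 0 passed and 3 were higher and 2 lower at an unadjusted p under 0.05, with a median of -0.05, a mean of 0.05 and no call (adjusted p = 0.738, and adjusted p = 0.924 with an estimated correlation). The skeletal muscle list averaged 2.00, 3.77 and 1.75 and the adipocyte list 0.72, 3.30 and 0.72 on the 3 arrays, so replicate 2 stood apart in both. Without it the macrophage (0.35), adipocyte (0.41) and skeletal muscle (0.50) shifts had no call, nor had macrophage (0.39) without replicate 3 without reflux. No scan day held both groups, and the differences correlated at 0.532 with that between days within Nrf2-null without reflux, so reflux cannot be told apart from scan day. With scan day as a block 7 genes passed and the shifts were 0.80, 0.55, 0.94, 0.86, 0.97 and, for Nrf2 targets, 0.01. The count was 7 and 5 without wild type without reflux replicates 1 and 2, 2 in a fit of only these arrays, 108 with the muscle list as a covariate and 30 with the scanner software's processed signals.

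Gastric reflux in the Nrf2-null oesophagus raised 86 genes and lowered 27. Liver transcripts again led the rises: Fabp1 (at least 94.7-fold), Ambp (5.95 ± 0.78, adjusted p = 0.0044), and the fibrinogen chains Fgg (at least 30.1-fold) and Fgb (5.27 ± 0.75). Ahsg (5.11 ± 0.50, 0.000244) and Mup1 (at least 21.8-fold) rose as well, and so did Alb (4.35 ± 0.71). Rab27a (-2.22 ± 0.27, 0.00282), Ccn3 (-1.45 ± 0.28), Wnt2 (-1.41 ± 0.27), Depp1 (-1.40 ± 0.26), Cap1 (-1.35 ± 0.18) and Irf2bpl (-1.32 ± 0.26) were among the largest falls. Of 30 cell cycle genes 1 rose (12 adjusted over the list alone), Cdc20 (0.94 ± 0.19), and Cenpa differed by 0.87 ± 0.20. Of 18 hypoxia and glycolysis genes 1 fell (3 adjusted over the list alone), Ndrg1 (-0.86 ± 0.16), and Pgam1 differed by -0.80. Of 15 circadian clock genes 1 fell (3 adjusted over the list alone), Per1 (-1.23 ± 0.26), and Nr1d1 differed by -1.04.

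No fibroblast, interferon-stimulated or Nrf2 target gene passed there in limma's test. At an unadjusted p under 0.05, 6 of 19 fibroblast genes were lower, 8 of 28 interferon-stimulated genes higher, and 2 Nrf2 targets higher and 4 lower. Fn1 and Col6a1 differed by -0.66 and -0.94, Oas3 and Mx2 by 0.98 and 1.85, and Gsta3 and Gstm1 by 0.79 and -0.55. The interferon list averaged 2.18 on replicate 3 and -0.71 and -1.55 on replicates 1 and 2, and its shift of 0.89 became -0.22 without replicate 3. Neutrophil, T and NK cell, MHC class II, adipocyte, NF-kB and squamous genes differed by 0.59, 0.60, 0.51, 1.095, 0.46 and 0.44 on average without a member that passed, with adjusted p of 0.0188, 0.00585, 0.0235, 0.0312, 0.00328 and 0.00256, and adjusted p of 0.619 to 0.643 with an estimated correlation. The other shifts were 0.32 for the cell cycle, -0.82 for fibroblast, -0.43 for hypoxia, -0.34 for clock and -0.12 for Nrf2 target genes. The adjusted p were 1.33e-06 for the cell cycle, 1.63e-05 for fibroblast, 7.79e-05 for hypoxia, 0.000538 for interferon, 0.00167 for clock and 0.106 for Nrf2 target genes, and adjusted p of 0.237, 0.619, 0.134, 0.733, 0.237 and 0.733 with an estimated correlation. Within day 3, which held 1 array without reflux, 8 genes passed, within slide 5 with 1 array of each group 3177, with scan day as a block 15 and with slide as a block 3180. The shifts for cell cycle, fibroblast, hypoxia, interferon, clock and Nrf2 target genes were 0.27, -0.95, -0.44, 0.08 (adjusted p = 0.71), -0.37 and -0.14 with the day block, and 0.23 (0.0537), -1.02 (0.0503), -0.59, -0.66 (0.371), -0.35 (0.125) and -0.39 with the slide block. The count was 14, 11 and 499 without Nrf2-null without reflux replicates 1, 2 and 3, 291 and 420 without gastric reflux replicates 2 (the array at odds with its label) and 3, and 56 after median centring.

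Duodenal reflux in the Nrf2-null oesophagus raised 2751 genes and lowered 1270. S100a8 (7.62 ± 0.80, adjusted p = 1.95e-05), Uox (6.87 ± 0.85), Spink12 (6.57 ± 0.91), and Il1b (5.97 ± 0.80, 0.00013) rose most. Slc26a4 (at least 49.6-fold), Fabp1 (at least 26.8-fold), Ltf (5.35 ± 0.73) and Nat8l (5.34 ± 0.70) followed, and Alb rose by 3.42 ± 0.71. Krt1 (-3.52 ± 0.74, 0.00349), Pof1b (-3.05 ± 0.89), Slc9a3 (-2.55 ± 0.52) and the matrix gene Efemp1 (-2.38 ± 0.23, 2.18e-05) fell most. From the deposited value table Pof1b differed by 1.38. Of 27 NF-kB targets 21 rose and 0 fell (21 and 1 adjusted over the list alone), including Ccl20 (3.08 ± 0.22, 6.9e-07), Csf3 (4.43 ± 0.39) and Cxcl1 (3.45 ± 0.39). Of 22 wounded epithelium genes 16 rose and 0 fell (17 rose adjusted over the list alone), including Il24 (2.83 ± 0.18, 2.69e-07), Mmp13 (3.92 ± 0.36) and Krt16 (4.41 ± 0.47). Among 16 neutrophil genes 11 rose and 0 fell (11 rose adjusted over the list alone), including Csf3r (at least 6.03-fold) and Retnlg (at least 9.22-fold).

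Some proliferation and differentiation genes rose too. Of 30 cell cycle genes 16 rose and 0 fell (18 rose adjusted over the list alone), with Rrm2 (2.18 ± 0.25, adjusted p = 4.3e-05), Mcm4 (1.56 ± 0.22) and Mcm2 (1.23 ± 0.19). Of 29 squamous differentiation genes 16 rose and 1 fell (17 and 4 adjusted over the list alone), with the suprabasal keratin Krt13 (1.48 ± 0.33), filaggrin Flg (0.81 ± 0.18) and Sprr3 (0.87 ± 0.20). Of 37 Nrf2 targets 3 rose and 7 fell (3 and 8 adjusted over the list alone): glutathione reductase Gsr (2.09 ± 0.15, 1.3e-06) and Akr1b8 (1.54 ± 0.22) rose, and Gstm1 (-1.72 ± 0.16) and Gstm3 (-1.61 ± 0.19) fell. The shifts were 1.56 for NF-kB, 1.60 for wounded epithelium, 0.49 for the cell cycle, 1.83 for neutrophil, 0.49 for squamous and -0.23 for Nrf2 target genes, with adjusted p of 1.17e-11, 3.6e-09, 2e-06, 3.54e-06, 0.00592 and 0.0318, and adjusted p of 0.159, 0.0603, 0.237, 0.237, 0.657 and 0.657 with an estimated correlation. Smooth muscle genes averaged 1.76 (0.59 on replicate 2) against 2.66 without reflux (1 of 10 lower, adjusted p = 0.00663), endothelial genes 2.99 against 2.17 (8 of 15 higher, 0.00663) and MHC class II genes 2.26 against 1.51 (4 of 9 higher, 0.0318), each with adjusted p = 0.657 with an estimated correlation. The smooth muscle call was lost without replicate 2, without the 2 arrays of low Cy5 signal and with slide as a block, and that of MHC class II was lost in 7 and turned in 1 of 23 alternatives.

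Within day 3, which held 1 array without reflux, 526 genes passed, and 1467 with scan day and 7506 with slide as a block. The shifts in the order above were 1.48, 1.53, 0.45, 1.77, 0.45 and -0.24 with the day block and 1.86, 1.08, 0.39 (adjusted p = 0.0764), 2.34, 1.14 and -0.66 with the slide block. Without duodenal reflux replicate 2 the squamous (0.23) and Nrf2 target (-0.18) shifts had no call. The Nrf2 target call was lost in 7 of 23 alternatives, among them the processed signals, median centring and the deposited value table. The count was 2353 and 2037 without Nrf2-null without reflux replicates 1 and 2, 2617 without duodenal reflux replicate 2, and 2036 after median centring (754 higher and 1282 lower, with the median of all genes at -0.17 against 0.08).

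Mixed reflux in the Nrf2-null oesophagus was compared as 1 sample against 3, and 704 genes were higher and 262 lower. S100a8 (7.31 ± 1.12, adjusted p = 0.00109), Spink12 (6.23 ± 1.29), Uox (6.05 ± 1.20) and Slc26a4 (5.89 ± 1.02) were highest. The chemokine Cxcl3 (at least 22.8-fold), Aldh1a3 (5.65 ± 1.09) and Il1b (5.56 ± 1.13) followed, while Alb did not pass (at least 1.27-fold, adjusted p = 0.667). The complement gene C7 (at least 7.05-fold lower), Efemp1 (-2.57 ± 0.33, 0.000577), F13a1 (-2.51 ± 0.68), Adh7 (-2.42 ± 0.44), Lrrc17 (-2.32 ± 0.44) and Pcdhb8 (-2.27 ± 0.55) were lowest. Of 10 smooth muscle genes 2 were lower (4 adjusted over the list alone), calponin Cnn1 (-2.26 ± 0.40) and Tagln (-2.26 ± 0.43), and Acta2 differed by -1.99 ± 0.61. That sample is labelled epithelium and the others whole oesophagus. An effect of reflux thus cannot be told apart from the tissue taken, least of all in muscle and matrix genes. Of 30 cell cycle genes 12 were higher (20 adjusted over the list alone), with Mcm6 (1.57 ± 0.22) and Mcm4 (2.30 ± 0.31).

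Of 27 NF-kB targets 10 were higher in that comparison (17 adjusted over the list alone), with Cxcl1 (4.24 ± 0.55, adjusted p = 0.000395), Csf3 (4.14 ± 0.56) and Ccl20 (2.31 ± 0.32). Of 22 wounded epithelium genes 10 were higher (11 adjusted over the list alone), with Il24 (3.099 ± 0.25, 1.48e-05), Mmp13 (4.61 ± 0.51) and Mmp10 (5.26 ± 0.81). Of 16 neutrophil genes 8 were higher (10 adjusted over the list alone), with Retnlg (at least 22.3-fold), Mmp8 (at least 5.47-fold) and Csf3r (at least 7.62-fold). Of 37 Nrf2 targets 2 were higher, Gsr (2.22 ± 0.22, 5.09e-05) and Akr1b8 (2.03 ± 0.31), and 4 lower, including Gstm1 (-1.58 ± 0.22) and Gstm2 (-1.87 ± 0.28), with the same numbers adjusted over the list alone. The list mean was 0.02, its shift -0.02 and it had no call (adjusted p = 0.485, and adjusted p = 0.932 with an estimated correlation). The shifts were 0.91 for the cell cycle, 1.61 for NF-kB, 1.70 for wounded epithelium, 2.05 for neutrophil and -1.50 for smooth muscle genes, with adjusted p of 1.9e-15, 2.25e-12, 2.32e-10, 2.19e-08 and 6.25e-05, and adjusted p of 0.0361, 0.0677, 0.0361, 0.0677 and 0.309 with an estimated correlation. Within day 3, which held 1 array without reflux, 247 genes passed, with scan day as a block 574 and with slide as a block 1342. The shifts in that order were 0.87, 1.54, 1.64, 1.99 and -1.45 with the day block and 0.82, 1.87, 1.09, 2.42 and -2.57 with the slide block, and for Nrf2 targets -0.03 and -0.50 (adjusted p = 0.0427). The count was 584 and 576 without Nrf2-null without reflux replicates 1 and 2, 446 after median centring and 5019 with the mixed reflux arrays as 3 samples. Endothelial genes differed by 0.73 on average (0 of 15 higher, adjusted p = 0.0157, and adjusted p = 0.927 with an estimated correlation).

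The genotype difference depended on reflux for 900 genes in the F test, and for 368 to 3064 with 1 sample left out, 290 after median centring and 4381 with Nrf2-null mixed reflux as 3 samples. Against the difference without reflux, it was more positive for 320 and more negative for 148 genes under gastric, for 50 and 22 under duodenal and for 229 and 74 under mixed reflux. Glutathione reductase Gsr (adjusted p = 0.000755) averaged -1.26, -0.74, -0.65 and -1.17 in the wild type without and with gastric, duodenal and mixed reflux, and -2.01, -1.86, 0.08 and 0.21 in the null. Cd163 (0.000755), in the same order, averaged 4.37, 4.51, 1.40 and 4.66 in the wild type and 4.73, 4.46, 4.91 and 3.21 in the null, so its fall under duodenal reflux was in the wild type. The sterol pathway isomerase gene Idi2 (0.000755), not above background in the wild type without reflux, averaged 0.24, 3.67 and 0.73 there under gastric, duodenal and mixed reflux, against 0.25, 0.30, 2.43 and 4.15, and the replication factor Cdc45 (0.000755) -2.70, -2.88, -1.97 and -3.15 against -2.93, -2.42, -2.53 and -1.37. The cytokine Il24 (0.000773) averaged 0.36, 0.10, 1.57 and 0.77 against 0.34, 0.36, 3.17 and 3.44, and Spink4 (0.00152), not above background in the wild type without or with gastric reflux, 0.65 and 0.28 under duodenal and mixed reflux against 2.38 and 2.00. Rps7-ps2 (0.000962) and Slc22a29 (0.00111, not above background in 5 groups) passed too. Under a scan day block 114 genes passed this test.

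Calls were set side by side between comparisons that have no array in common. Of the genes raised by duodenal reflux, 746 were shared between genotypes, where independent lists would share 176, and of those lowered 310, against 46.8. Gastric reflux raised 32 genes in both genotypes (2.52 for independent lists) and lowered 1 (0.49), while 8 fell in the wild type and rose in the null (1.56), and mixed reflux raised 4 (0.308). Between genotypes, 57 genes were higher in the null under both duodenal and mixed reflux (5.83) and 29 lower (1.66), and 10 were lower under duodenal but higher under mixed reflux (3.32).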

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

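The tests of the 3 patterns below were chosen after the patterns were seen, and the skeletal muscle covariate and the scan day block after the data were seen. Of the genes named in the report, 69 had a genotype difference that differed between reflux conditions in the F test (limma). In the cell cycle and replication the adjusted p was Aurkb 0.0169, Birc5 0.0194, Bub1 0.0487, Ccna2 0.0249, Cdc20 0.0129, Cdc45 0.000755, Cenpa 0.0111, Cks2 0.0112, Mcm2 0.0151, Mcm3 0.00764, Mcm4 0.0397, Mcm5 0.018, Mcm6 0.00584, Plk1 0.042, Rrm1 0.0324 and Tpx2 0.00933. Among cytokines and growth factors it was Areg 0.0453, Ccl20 0.0256, Csf3 0.0331, Cxcl1 0.0254, Cxcl2 0.0437, Cxcl3 0.0158, Il24 0.000773, Il6 0.0309, Pf4 0.041, Ppbp 0.0389 and Wnt2 0.00587. Among leukocyte and matrix genes it was Cd163 0.000755, Cilp 0.0433, F13a1 0.0149, Fbn1 0.042, Has1 0.044, Lrrc17 0.00959, Mmp13 0.0089, Mmp8 0.0451, Mmp9 0.0368, Retnla 0.0145 and Retnlg 0.0386. Among redox and lipid genes it was Akr1b8 0.00646, Akr1c18 0.00587, Aldh1a3 0.0362, Fmo9 0.00843, Gsr 0.000755, Gsta3 0.0177, Gstm2 0.0129, Idi2 0.000755, Mboat2 0.0451 and Pbp2 0.00431. Among muscle, membrane and clock genes it was Cap1 0.00843, Ccn3 0.01, Clec2d 0.0296, Cnn1 0.0221, Mal 0.0452, Nr1d1 0.045, Rab27a 0.0151, S100g 0.0131, Tagln 0.0384 and Upk3bl 0.0172. Among the others it was 0610040J01Rik 0.0202, Arc 0.0327, Bhlhe22 0.0324, Fer1l4 0.0232, Irf2bpl 0.042, Natd1 0.0221, Pcdhb8 0.0174, Prap1 0.0075, Rps7-ps2 0.000962, Slc22a29 0.00111 and Spink4 0.00152.

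Albumin was not above background on any array without reflux, and its ratio was higher by 3.56 ± 0.71 in the wild type under gastric and 4.12 ± 0.71 under duodenal reflux, against at least 65.1-fold and 33.2-fold in Cy5 alone, a disagreement that could not be settled without a dye swap. RNA of intestinal epithelium stays open: 6 of its genes had a median correlation with albumin of 0.112. Some stayed low (Alpi) or were high without reflux (Slc5a1, 3.76). The intestinal list of 8 was shifted up in the null under gastric (adjusted p = 0.0448) and the wild type under mixed reflux. Liver RNA in the dissected tissue cannot be told apart from expression in the oesophagus: 9 intracellular liver genes had a median correlation of 0.569, between the bounds set for either answer. Fabp1 (0.972) followed albumin, while Rgn (0.262) and Arg1 (-0.006) were already at 3.59 and 5.58 without reflux. An effect of reflux itself was not tested.

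The genotypes differed in 3593 genes under gastric reflux and in 36 without (310 with the muscle list as a covariate, 247 without 2 arrays of low Cy5 signal and 3054 with local backgrounds as read). Skeletal muscle content as the whole cause is argued against by 4454 genes with the muscle list as a covariate, and the weak array of Nrf2-null gastric reflux replicate 1 by 5009 genes without it. Another split of the same 6 samples, wild type 1 with null 2 and 3 against wild type 2 and 3 with null 1, gave 3285 genes and follows the muscle list (0.65 to 1.80 against 4.52 to 4.65), which points to a structure of the samples. Scan day cannot be told apart from genotype, since no day held both groups: the difference correlated at 0.294 over genes with that between days within Nrf2-null without reflux (0.512 and 0.532 for duodenal and mixed reflux in the wild type). With scan day as a block 9 genes passed: the median size of the 3593 differences went from 0.846 to 0.618 and their median standard error from 0.211 to 0.361, so both moved, and a biological effect of gastric reflux on the genotype difference stays open.

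Rbm45, 705 kb from the Nfe2l2 probe, was higher in the null in each of the 4 conditions (3.16 ± 0.15 in the mean). DNA of the donor strain around the targeted gene predicts more called genes near it. Of 361 genes within 20 Mb, 30 were called in the mean (8.3%), against 1446 of 18428 on other chromosomes (7.8%), a ratio of 1.06 (1-sided Fisher's exact p = 0.401). The ratio lay between the bounds set for either answer, so this cannot be told apart for Rbm45 or the other 3 genes called within 5 Mb. A regulation of Rbm45 by Nrf2 stays open, as untested.

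Samples compared 3 against 3 were also split in every other way, and 10 splits are too few for a share under 0.05. The real count, the highest of the other splits and the number of splits with as many genes, the real one included, were: 36, 0 and 1 (genotype, no reflux), 3593, 3285 and 1 (genotype, gastric), 400, 0 and 1 (genotype, duodenal), 976, 209 and 1 (wild type, gastric), 2069, 1 and 1 (wild type, duodenal), 12, 0 and 1 (wild type, mixed), 113, 1247 and 2 (null, gastric) and 4021, 0 and 1 (null, duodenal). In the null under gastric reflux the larger split set null without reflux 1 and 2 with gastric reflux 1 against the rest. Its 1247 genes point to a structure of the samples. For the genotype mean, 1 of 100 splits, the real one, gave as many as 1605 genes (highest other 310), so chance can be excluded. For the dependence on reflux 1 of 100 gave as many as 900 (highest other 611). Those splits also broke up plain reflux effects, so chance stays open. Comparisons with Nrf2-null mixed reflux, 1 sample, were not split.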

How the results depend on the processing

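The scan day block, scan day taken alone, the arrays of low Cy5 signal left out, the skeletal muscle covariate, outlier spots kept, local backgrounds as read and the Nrf2-null mixed reflux arrays as 3 samples were chosen after seeing the data. Each of the other alternatives was chosen beforehand. Counts that moved by more than 1.5 times follow for each alternative (genotype, Nrf2-null against wild type; wild type or null, reflux against none; F test, dependence on reflux), and the cause was not tested. With the scanner software's processed signals counts were 30 (mixed) for the wild type and 527 for the F test. After median centring counts were 1895 (gastric), 29 (duodenal), 341 (mixed) and 847 (mean) for the genotype, 3087 (gastric) for the wild type, 56 (gastric), 2036 (duodenal) and 446 (mixed) for the null, and 290 for the F test. From the deposited value table counts were 448 (mixed) for the genotype and 538 for the F test. In fits of only the 2 groups compared counts were 1 (gastric), 747 (duodenal) and 1 (mixed) for the genotype, 633 (gastric), 6651 (duodenal) and 2 (mixed) for the wild type, and 9 (gastric) and 1466 (mixed) for the null. With slide as a random block counts were 2253 (gastric), 223 (duodenal) and 994 (mean) for the genotype, 534 (gastric) and 6 (mixed) for the wild type, 73 (gastric) for the null, and 496 for the F test. With slide as a fixed block counts were 5187 (duodenal) for the genotype, 38 (gastric) for the wild type, and 3180 (gastric) and 7506 (duodenal) for the null. Without slide 1 counts were 22 (no reflux) for the genotype, 16 (gastric) and 443 (duodenal) for the wild type, and 318 for the F test. With local backgrounds as read counts were 3054 (no reflux) for the genotype, 3653 (gastric), 4218 (duodenal) and 2935 (mixed) for the wild type, and 2959 for the F test. With Nrf2-null mixed reflux as 3 samples counts were 59 (no reflux), 814 (duodenal), 4317 (mixed) and 3727 (mean) for the genotype, 1823 (gastric) and 31 (mixed) for the wild type, 435 (gastric) and 5019 (mixed) for the null, and 4381 for the F test. With scan day as a fixed block counts were 16 (no reflux), 9 (gastric), 2676 (duodenal), 1165 (mixed) and 216 (mean) for the genotype, 10 (gastric), 15 (duodenal) and 7 (mixed) for the wild type, 15 (gastric), 1467 (duodenal) and 574 (mixed) for the null, and 114 for the F test. Without the 2 arrays of low Cy5 signal counts were 247 (no reflux), 6538 (gastric), 763 (duodenal), 2649 (mixed) and 4817 (mean) for the genotype, 3715 (gastric), 4547 (duodenal) and 147 (mixed) for the wild type, 494 (gastric) and 2697 (mixed) for the null, and 3544 for the F test. With the skeletal muscle list as a covariate counts were 310 (no reflux) and 2973 (mean) for the genotype, 131 (gastric) and 108 (mixed) for the wild type, 268 (gastric) for the null, and 1714 for the F test. With outlier spots kept counts were 1737 (gastric) and 29 (mixed) for the wild type. Within slide 2 the count was 15 (gastric) for the wild type. Within slide 5 the count was 3177 (gastric) for the null. Within scan day 2 counts were 19 (no reflux) for the genotype and 12 (gastric) for the wild type. Within scan day 3 counts were 8 (gastric), 526 (duodenal) and 247 (mixed) for the null.

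Aquantile normalisation changed no value. Counts without the filter on dim probes and with the mean of a gene's probes stayed within 1.5 times in each comparison. With a replicate block the counts were 261 (duodenal) for the genotype, 58 (gastric) for the null, and 510 for the F test, and the other counts stayed within 1.5 times. The replicate numbers were checked for pairing: deviations of same-numbered samples correlated at -0.021 on average (-0.653 to 0.569), 16 of 63 pairs were over 0.1, and 5 of 21 samples were closest to one of their own number. The samples were therefore read as sharing only a number. The fit of only the 2 groups was not run for the genotype mean and the dependence on reflux.

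Leaving out each sample in turn gave 17 to 27 against 36 (no reflux), 1021 to 5009 against 3593 (gastric), 98 to 298 against 400 (duodenal), 326 to 963 against 705 (mixed) and 1012 to 3237 against 1605 (mean) for the genotype. It gave 25 to 2663 against 976 (gastric), 884 to 1605 against 2069 (duodenal) and 5 to 10 against 12 (mixed) for the wild type, 11 to 499 against 113 (gastric), 2037 to 3535 against 4021 (duodenal) and 576 to 1112 against 966 (mixed) for the null, and 368 to 3064 against 900 for the F test. A lone sample left in a group is assumed to vary like the other groups. Without a replicate of the wild type the F test count was 566 and 500 (no reflux 1 and 2), 2620, 386 and 401 (gastric 1, 2 and 3), 466, 422 and 368 (duodenal 1, 2 and 3) and 518, 1376 and 478 (mixed 1, 2 and 3), and of the null 518 and 404 (no reflux 1 and 2), 3064 (gastric 1) and 585 (duodenal 3).

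Of the values for named genes without 1 sample, 2587 kept direction and side of the threshold, 274 lost the call and 25 gained it. With the scan day block these were 238, 150 and 5, and for lists 59 kept and 2 lost the call. Of the 394 gene results, 67 calls were kept under each alternative run, 229 were lost under at least 1, 8 turned and 90 results had no call. The direction turned for Csf3r in wild-type duodenal reflux (-0.334) and Pof1b in null duodenal reflux (1.375) from the deposited value table. For Dst in wild-type gastric reflux it turned with the mean of its probes (1.045), and for Tpx2 there after median centring (0.093). Esam in wild-type duodenal reflux turned with the scan day block (-0.16), and Fmo9 in the genotype comparison under duodenal reflux with the processed signals (0.508). With local backgrounds as read, Lamb3 (0.159), Trp63 (1.222) and the basal keratinocyte list (0.116) turned in wild-type gastric reflux, and Wfdc21 (0.114) in wild-type duodenal reflux. The shift of the wounded epithelium list in the duodenal genotype comparison turned with slide as a fixed block (-0.17), but not the direction of its test. The interferon-stimulated genes list in null gastric reflux was -0.655 with slide as a fixed block and within slide 5, and -0.216 to 1.629 with 1 sample left out, the lowest without Nrf2-null gastric reflux replicate 3. With the muscle covariate, built from its own members, the skeletal muscle list was -0.173 (genotype without reflux), -0.189 (wild-type gastric reflux) and -0.275 (wild-type mixed reflux). The cause of the other turns was not tested.

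Where the scaling moved the share of called genes that were higher by over 10 points, it was 22.6% against 44.4% (genotype, no reflux, processed signals), 51.7% against 63.8% (genotype, duodenal), 53.6% against 63.8% (genotype, duodenal, value table), 77.7% against 66.7% (genotype, mixed), 81.1% against 68% (genotype mean), 50% against 61.8% (wild type, gastric, processed signals) and 100% against 75% (wild type, mixed), each after median centring unless another scaling is named. Where either passed 0.1, the median of all genes after centring was 0.15 against 0.007 (genotype, mixed) and 0.285 against 0.046 (wild type, mixed), and the report gives the other shares and medians. The direction of a small difference therefore depends on the scaling where these medians part.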

Other observations

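The lists and comparisons were chosen beforehand, and the values of single arrays below were picked after they were seen. T and NK cell genes were shifted upwards in the wild type under duodenal reflux (6 of 17 higher and 0 lower, adjusted p = 0.00151, and adjusted p = 0.755 with an estimated correlation). Immediate early genes were shifted upwards in the null under duodenal reflux (7 of 14 higher and 0 lower, adjusted p = 0.0115, and adjusted p = 0.545 with an estimated correlation) and under mixed reflux (4 of 14 higher and 1 lower, adjusted p = 0.00119, and adjusted p = 0.309 with an estimated correlation). Columnar keratins and their regulators were shifted downwards in the null under mixed reflux (0 of 13 higher and 2 lower, adjusted p = 0.0025, and adjusted p = 0.0475 with an estimated correlation), a group of 1 sample.

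Sterol biosynthesis genes were shifted downwards in the null under duodenal reflux (0 of 17 higher and 2 lower, adjusted p = 0.0281, and adjusted p = 0.657 with an estimated correlation), lost in 6 of 23 alternatives. Unfolded protein response genes were shifted upwards in the null in the mean over conditions (2 of 13 higher and 0 lower, adjusted p = 0.0413, and adjusted p = 0.247 with an estimated correlation), a call lost in 9 of 39 alternatives, and downwards in the null under gastric reflux (0 of 13 higher and 0 lower (1 and 3 at an unadjusted p under 0.05), adjusted p = 0.0312, and adjusted p = 0.303 with an estimated correlation), lost in 7 of 24 alternatives. Intestinal epithelium genes were shifted upwards in the wild type under mixed reflux (0 of 8 higher and 0 lower (3 and 0 at an unadjusted p under 0.05), adjusted p = 0.00355, and adjusted p = 0.153 with an estimated correlation) and in the null under gastric reflux (1 of 8 higher and 0 lower, adjusted p = 0.0448, and adjusted p = 0.237 with an estimated correlation), the latter lost in 7 of 24 alternatives.

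Each of the other 8 lists (B and plasma cell, bile acid and Ah receptor response, desmosome and adherens junction, gastric epithelium, ion and acid transport, p53 target genes, thyroid and airway and tight junction) had no call in the 11 comparisons (smallest adjusted p = 0.0617).

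Nrf2-null gastric reflux replicate 2, labelled male, had Ddx3y at -4.20 (0.16 to 1.48 on the other arrays), Eif2s3y at -4.09 (1.468 to 3.095) and Kdm5d at -1.58 (0.14 to 1.66), all on the Y chromosome, and Xist at -1.78 (-7.20 to -4.61), so the label or the sample is in doubt. Nrf2-null gastric reflux replicate 3 had an interferon list mean of 2.18, against -1.63 to -0.13 on the other arrays.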
